A study of Homo sapiens with 2 samples.

How the data were processed

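Expression was measured on arrays in primary human keratinocytes grown from sole skin. 1 isolate was cultured in KGM-GOLD, a commercial keratinocyte growth medium, and harvested at passage 4 and at passage 8, with no other treatment, per the labels' protocols. Total RNA was purified on RNeasy columns, and biotin-labelled cRNA was made with a kit that primes from the 3′ end of transcripts, per the labels' protocols. Each passage was hybridised to 1 array, which gives 2 arrays in all.

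The deposited values are on the log2 scale, 1 value per probe set and array. Partek and RMA are named, without version or settings, per the submitters' processing notes. RMA, by its usual definition, corrects background, makes the probe distributions of arrays alike by quantile normalization, and summarises each probe set on the log2 scale. Because it aligns distributions, a global shift in expression between the passages cannot be seen in such values, and differences at low signal are compressed. Which arrays were normalized together is not given in the sources used here. The platform's name and a genome build are likewise not given in the sources used here, so no coordinates are printed.

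The table held 49395 probe sets, of which 102 were controls. Through GEO's platform annotation, 45064 probe sets had 1 gene symbol, 1756 had several and 2473 had none. Entrez identifiers matched 44961 of the 45064 to the reference gene table, and 0 symbols changed. No gene was named from a probe set tied to several genes. Genes whose level could point to the sex of a person were left out throughout. The probe set with the highest mean over both arrays stood for a gene, which gave 18140 genes. A gene counted as measured where at least 1 array reached the median of all non-control probe sets, log2 5.72, and 10532 genes did. This floor is a convention and not a detection test, and it stands in for signal over background. The number of arrays limits the precision of every value.

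With 1 array per passage there are 0 residual degrees of freedom, so no test, p-value or standard error was possible. The log2 difference, passage 8 minus passage 4, was computed per gene, and genes were counted at 2-fold or more in each direction. For each of 43 gene lists, which held 965 distinct genes, the median difference over measured members was set against 10000 random lists of the same size, matched on mean level in 20 bins. A list stood apart where its median lay at or below percentile 2.5 or at or above percentile 97.5 of those random medians, which describes these arrays only. Lists with under 5 measured members have no percentile. Of the 965 genes, 886 had a probe set of their own and 661 were measured. The remaining 79, among them TP63, KRT6A, KRT16, KRT17 and HOXA13, were not analysed here.

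The lists, the floor, the threshold, the rule for naming genes and the alternatives were fixed before the data were examined, except where a choice is said to have come later. By that rule the text names the 12 genes highest and the 12 lowest by difference, among those whose measured probe sets all went the same way, and KRT9. In each list it names up to 4 members past 2-fold or, where none reached it, the 2 with the largest absolute difference, and for other cell types also the 2 with the highest level. The rule gave 96 genes. Any other gene named as a further member of a group was chosen after its value was seen.

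Alternatives recomputed the counts, list medians and named genes after centring each array on its median, after quantile normalization of the 2 arrays, and after subtracting a lowess curve (fraction 0.3). Another took the median level of all probe sets of a gene on each array and subtracted these levels. This is not the median of the probe sets' differences, and the levels can come from different probe sets. Others left out probe sets that can cross-hybridise (marked _x_at or _s_at), or moved the floor to percentile 25 or 75 or dropped it. Thresholds of 1.5-fold and 3-fold were used too. Random lists were also drawn without matching on level. Agreement between probe sets of a gene was counted as a check of probes, not of replication.

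The calculations were tested on simulated data first. Noise was drawn independently per probe set, so that differences had the SD of the spiked control transcripts, 0.10. Differences of the real measured genes had a robust SD (from the median absolute deviation) of 0.21. The simulation thus checks the calculation and gives no rate of false calls for these arrays. Among 18140 simulated genes, 50 of 50 changed by 3-fold passed the 2-fold threshold, 0 of 50 changed by 1.5-fold did, and 0 of 10206 unchanged genes passed. Among 10406 measured genes in the simulation, 50 of 50 lists raised by 0.3 on the log2 scale stood apart as higher, and 10 of 200 unchanged lists stood apart. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.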

Results

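Keratinocytes cultured from the skin of the sole were profiled on 2 expression arrays, 1 at passage 4 and 1 at passage 8 of the same isolate. Volar skin, which covers palms and soles, is thick and hairless, and KRT9 is its characteristic keratin. The comparison addresses how the profile of these cells in culture differs between an early and a late passage. There are no replicates, so no difference carries a p-value or an error between cultures, and each value describes these 2 arrays. The median probe set lay at log2 5.71 at passage 4 and at 5.73 at passage 8, and 10213 and 10385 genes reached the floor of 5.72. Spiked control transcripts, added in equal amounts by design, differed between the arrays by a mean of 0.07 ± 0.10 on the log2 scale (SD, n = 27 probe sets), with a range of −0.16 to 0.23. The 3′ signal minus the 5′ signal, a sign of RNA quality, was 0.12 at passage 4 and 0.13 at passage 8 for ACTB, and 0.06 and −0.05 for GAPDH.

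FN1, which encodes the matrix glycoprotein fibronectin, was 42.1-fold higher at passage 8, with log2 values of 5.81 at passage 4, just over the floor, and 11.20 at passage 8. That is the largest difference among its 8 probe sets, which spanned 0.51 to 5.40 with a median of 4.44. The interferon-induced gene IFI27 was 11.6-fold higher by its brightest probe set, and its probe sets differed by 1.79 and 3.54. IFI6, also interferon-induced, was 8.89-fold higher, the chemokine CXCL14 was 4.80-fold higher, with probe sets from 0.04 to 2.35, and ISG15, a ubiquitin-like interferon product, was 4.28-fold higher. Other genes named for large differences lay below the floor at passage 4, so their folds are given as bounds, with the level at passage 4 raised to the floor, a choice made after the data were seen. MX1, an interferon-induced antiviral GTPase, was at least 4.48-fold higher, the matricellular protein POSTN at least 4.19-fold, and SAA1, an acute-phase protein, at least 3.43-fold. IFNK, which encodes the keratinocyte interferon kappa, was at least 3.13-fold higher, KRT7, a keratin of simple epithelia and glands, at least 2.73-fold, and the interferon-induced IFI44 at least 2.55-fold, with probe sets from 0.02 to 2.59. ALDH1A2, a retinoic acid synthesis enzyme, was at least 1.28-fold higher, so its 2-fold call rests on signal below the floor.

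Differences in the other direction were smaller. The cell division gene CDCA3 was lower at passage 8 by a log2 difference of −1.20, and BAMBI, a decoy receptor of TGF-beta family ligands, by −1.17. CTH, the cystathionine gamma-lyase of cysteine synthesis, differed by −1.10, NAV3 by −1.07 and the matrix glycoprotein TNC by −1.04. The rest lay below the floor at passage 8 and have bounds set in the same way. The non-coding genes DLEU2 and SNORA84 were at least 2.12-fold and 1.86-fold lower, the corneodesmosin gene CDSN at least 1.71-fold, ATAD5 at least 1.45-fold and TP53I11 at least 1.40-fold. The aquaglyceroporin AQP9 was at least 1.35-fold lower and the homeobox gene DLX5 at least 1.19-fold lower. Of these 7 genes, DLEU2 alone kept its 2-fold call against the floor. Probe sets disagreed for DLX5 (−1.47 and 0.20), AQP9 (−1.40 to 0.05), CDCA3 (−1.20 and 0.17) and DLEU2 (−1.13 to 0.02), and went the same way but unequally for NAV3 (−1.07 and −0.21) and TP53I11 (−1.05 to −0.14). For each of these genes, all probe sets but the brightest lay below the floor on both arrays, so these contrasts rest on dim signal. With the median of all probe sets, the last 6 genes and TNC lost their 2-fold calls.

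Of 10532 measured genes, 59 were at least 2-fold higher at passage 8 and 14 were at least 2-fold lower, so 80.8% of the genes past 2-fold were higher. At 3-fold the counts were 24 and 0, and at 1.5-fold they were 194 and 196, so 49.7% were higher there. The median difference over measured genes was −0.05, and the correlation between the arrays across probe sets was 0.994 (Pearson's r; probe sets are not independent replicates). Among 26 genes past 2-fold with several measured probe sets, the probe sets of 25 all went the same way, and LSP1, named after its value was seen, was the exception. Of the genes past 2-fold, 25 of the 59 lay below the floor at passage 4 and 8 of the 14 lay below it at passage 8, where a fold rests on dim signal. With levels below the floor set to the floor, 44 genes were at least 2-fold higher and 7 lower.

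**Figure D1:**
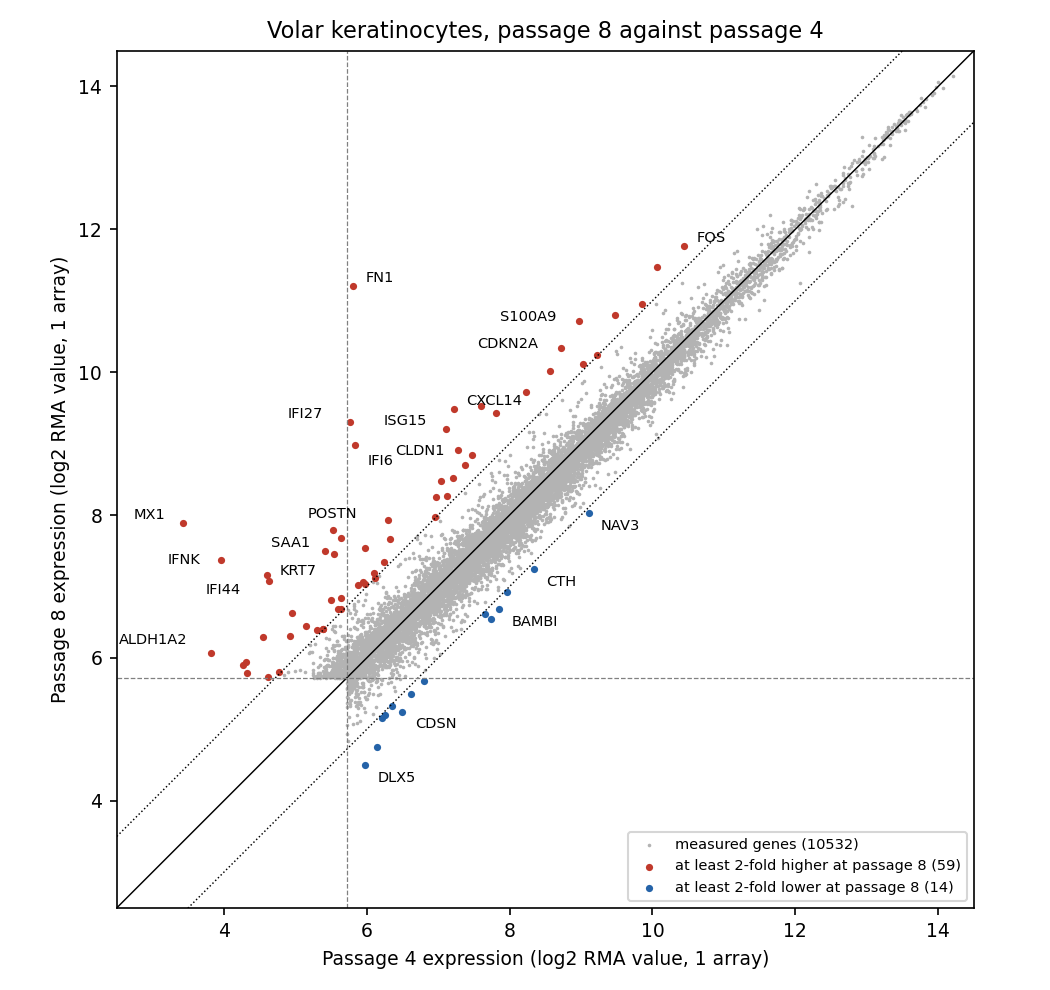
Each point is 1 of the 10532 measured genes, with its log2 RMA value at passage 4 on the x axis and at passage 8 on the y axis, 1 array each; dotted lines mark 2-fold, dashed lines the floor of 5.72. The 59 genes at least 2-fold higher (red) reach farther from the diagonal than the 14 lower ones (blue), and FN1 at 5.81 and 11.20 lies farthest from it.

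Interferon-stimulated genes were higher at passage 8 almost throughout the list. Of 27 measured members, 26 had a difference above 0, 12 were at least 2-fold higher and 0 were at least 2-fold lower. The list's median difference was 0.87, above all 10000 random lists, whose medians lay between −0.11 and 0.13 in 95% of draws. Apart from the members already given, IFIT1, which binds foreign RNA, and its binding partner IFIT3 were at least 3.88-fold and 1.88-fold higher against the floor and the RNA sensor RIGI at least 1.66-fold, while the membrane-associated antiviral IFITM1 differed by 1.33. The transcription factors IRF9 and IRF7, which act in interferon signalling and induction, differed by 1.32 and 0.84. EPSTI1 (−0.17) was the member below 0, and OAS1 differed by 0.03, with probe sets from −0.14 to 1.95, both named after their values were seen. The list supplied 12 of the 59 genes at least 2-fold higher, and 10 of these 12 stayed past 2-fold with low levels set to the floor. Antigen presentation genes, many of them also interferon-inducible, had a median of 0.08 (16 members, percentile 98.6). None of them reached 2-fold, and the largest difference was 0.43 for HLA-B, whose probe sets spanned 0.22 to 0.91, level with CD74, which was below the floor at passage 4 (at least 0.28 against it) and whose probe sets went both ways. That list no longer stood apart without probe sets that can cross-hybridise (percentile 95.1) or against random lists not matched on level (97.2).

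**Figure D2:**
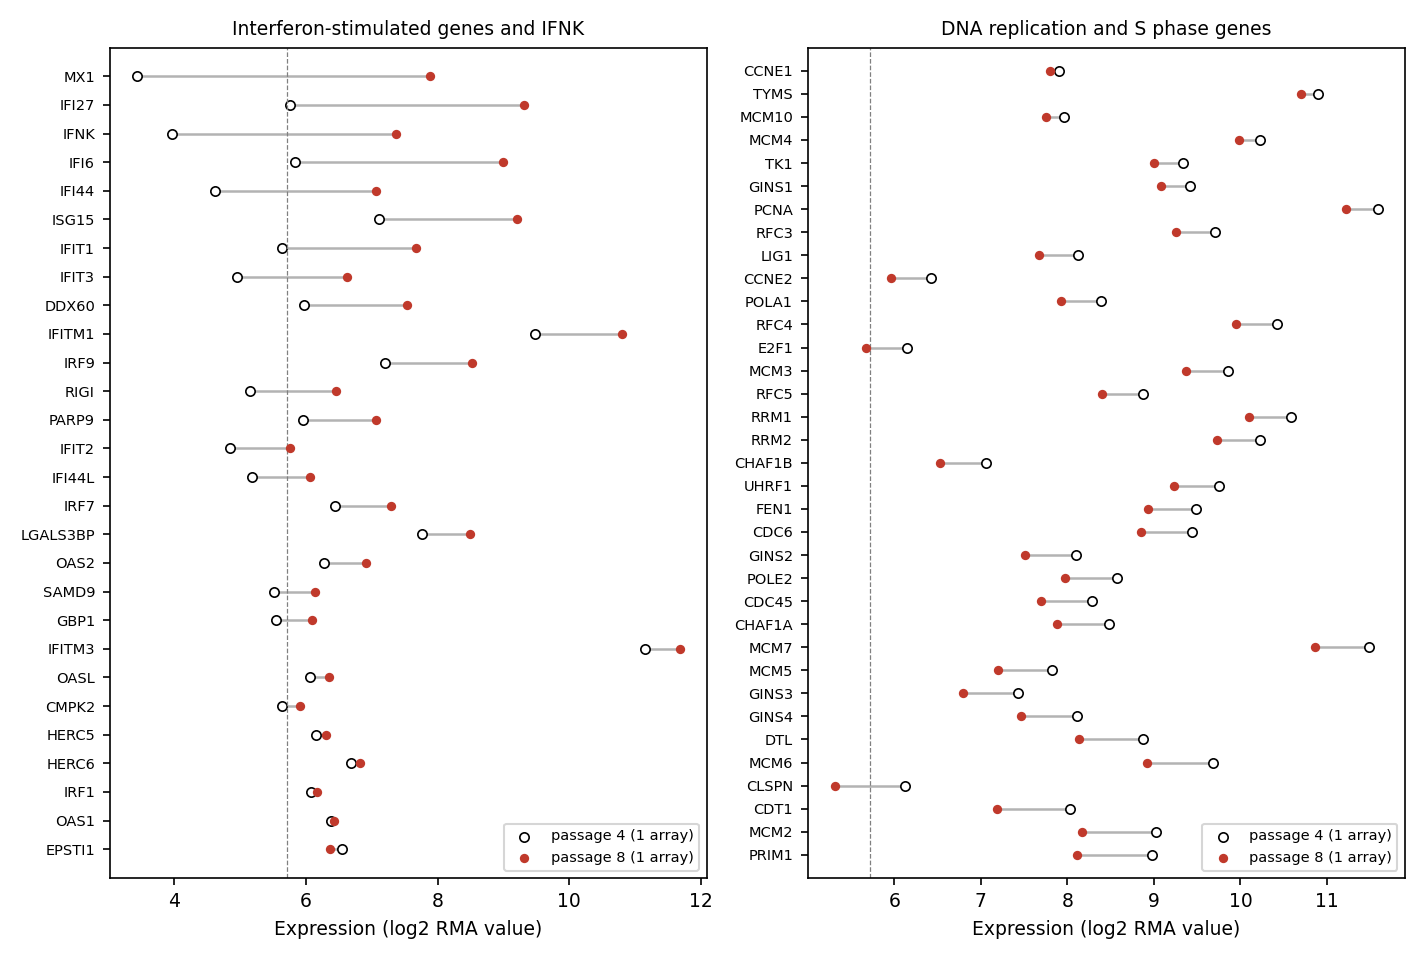
Log2 RMA values at passage 4 (open circles) and passage 8 (red circles), 1 array each, for the 27 measured interferon-stimulated genes with IFNK (left) and the 35 measured DNA replication and S phase genes (right), ordered by difference; the dashed line marks the floor of 5.72. Passage 8 lies to the right for 26 of the 27 interferon list members and for IFNK, and to the left for all 35 replication genes.

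Genes of DNA replication and of mitosis were lower at passage 8, each by less than 2-fold. All 35 measured replication and S phase genes had differences below 0, from −0.88 to −0.10, with a median of −0.52. All 35 measured G2 and mitosis genes did too, from −0.83 to −0.28, with a median of −0.50. Both medians lay below all 10000 random lists. PRIM1, the small subunit of DNA primase, and MCM2, part of the replicative helicase, differed by −0.88 and −0.85, and CDC25C and AURKB, both needed for mitosis, by −0.83 and −0.80. The proliferation marker MKI67 differed by −0.75. Nuclear genes that are known to be lower in senescent cells had a median of −0.42, with 12 of 12 members below 0. Among them were the chromatin remodeller HELLS (−0.54), the methylation maintenance factor UHRF1 (−0.52) and the lamin gene LMNB1 (−0.44). The S phase list also holds UHRF1, so these list results overlap.

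CDKN2A, the locus of the p16 inhibitor of cyclin-dependent kinases, was 3.10-fold higher at passage 8, from log2 8.71 to 10.34. Its 3 probe sets differed by 0.52, 1.24 and 1.63, and 2 of them were past 2-fold, so the size depends on the probe set. The 2-fold call was lost with the median level of all probe sets on each array (0.52). That level came from the probe set with the smallest difference. In the list of kinase inhibitors and senescence-raised genes, 9 of 14 members were above 0 and the median was 0.26 (percentile 100). The neighbouring inhibitor CDKN2B differed by 0.89 and CDKN1A, a p53 target, by 0.33. Targets of p53 had a median of 0.17 (27 members, 20 above 0, percentile 100). TP53INP1, a stress-induced p53 cofactor, was the member past 2-fold, with a difference of 1.28 for its brightest probe set and 0.51 for the other. Its call was lost with the median of all probe sets (0.90).

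Basal layer and hemidesmosome genes did not stand apart (19 members, median 0.01, percentile 84.9). KRT5 and KRT14, the keratins of basal cells, differed by −0.03 and −0.05. KRT15, a keratin of some basal cells, differed by 0.84 and ASS1 by 0.43. Spinous layer genes had a median of 0.10 (22 members, percentile 99.5) with none past 2-fold. The cornified envelope precursor IVL differed by 0.83. GRHL3, a transcription factor of barrier formation, lay below the floor at passage 4 and was higher by at least 0.081 against it, while the early keratins KRT1 and KRT10 differed by 0.55 and −0.19. That list stopped standing apart without probe sets that can cross-hybridise (percentile 96.9) and with the floor at percentile 75 (94.7). Granular layer genes had a median of 0.14 (22 members, percentile 97.4), which did not pass the bound, although they passed it under 5 of 9 alternative settings. Their members past 2-fold went in both directions, with 1.14 for the cornified envelope gene LCE3D, whose probe sets differed by 0.04 and 1.14 and whose call was lost with their median (0.59), and a difference below the floor for CDSN (at least 1.71-fold lower).

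Wound keratins and epidermal alarmins stood apart, with a median of 0.39 and 10 of 12 members above 0 (percentile 100). The calprotectin subunits S100A9 and S100A8 were 3.35-fold and 2.65-fold higher, and the surface glycoprotein CD24 was 2.13-fold higher. Simple epithelial and luminal keratins had a median of 0.33 (8 members, 6 above 0), against random medians of −0.20 to 0.14. Only 4 of them were measured with the floor at percentile 75, too few for a call, with a median of 0.056. KRT19 was 2.53-fold higher beside KRT7. Epithelial junction genes did not stand apart (15 members, median 0.03, percentile 92.7), although the tight junction protein CLDN1 was 3.09-fold higher and all 4 of its probe sets passed 2-fold.

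Palmoplantar and site-identity genes did not stand apart (9 of 25 listed genes measured, median −0.05, percentile 41.5). The sign of that median turned under 4 alternatives, and it was 0.12 with the floor at percentile 25 (percentile 93.3) or with no floor (95.3). KRT9 differed by −0.29, from log2 6.32 to 6.03, close to the floor. WNT5A differed by −0.33. None of the 9 reached 2-fold.

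Among mesenchymal genes, FN1 and POSTN were more than 2-fold higher and TNC was more than 2-fold lower, and the list's median was 0.17 (18 members, percentile 100). 7 of 8 FN1 probe sets and 5 of 5 POSTN probe sets were at least 2-fold higher. For TNC, 1 of 4 probe sets passed 2-fold (−1.04 to −0.42), and its call was lost under quantile normalization (−0.98), lowess (−0.97) and the median of all probe sets (−0.76). Dermal fibroblast markers measured beside them were 5 in number with a median of 0.21 (just inside the random range of −0.29 to 0.21). COL6A1 differed by 0.85, with probe sets from 0.03 to 0.85, COL5A2 by 0.34 and TWIST2 by −0.33. Matrix proteases, their inhibitors and insulin-like growth factor binding proteins had a median of 0.35 (17 members, 14 above 0, percentile 100). IGFBP6 was 2.51-fold higher, ADAMTS1 and MMP9 differed by 0.94 and 0.86, and the interstitial collagenase MMP1 differed by −0.62.

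Secreted inflammatory and senescence-associated factors had a median of 0.20 (15 members, 10 above 0), against random medians of −0.17 to 0.11. CXCL14 and SAA1 were the members past 2-fold. The cytokine genes IL1A and IL1B differed by −0.09 and −0.11, and CXCL8, below the floor at passage 4, by at least 0.063 against it. The list stopped standing apart with the floor at percentile 75 (median −0.01), with no floor (percentile 96.5) and without probe sets that can cross-hybridise (percentile 94.6). TGF-beta response genes had a median of 0.09 (20 members, percentile 99.8). LTBP1, which tethers latent TGF-beta to the matrix, was 2.84-fold higher, the BMP-responsive ID3 was 2.03-fold higher and BAMBI was lower. For ID3, 1 of 3 probe sets passed 2-fold, and its call was lost (0.96) with the median of all probe sets and without probe sets that can cross-hybridise. That list did not stand apart with the median of all probe sets (percentile 93.2) or without probe sets that can cross-hybridise (93.3).

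Immediate early and AP-1 genes had a median of 0.16 (22 members, 15 above 0, percentile 100). The phosphatase gene DUSP1 was 2.58-fold higher and FOS was 2.49-fold higher, while FOSL1 differed by −0.74, with probe sets from −0.74 to 0.05. EGF receptor family genes and ligands did not stand apart (20 members, median −0.04, percentile 63.4). The ligands NRG1 (probe sets −0.91 to 0.10) and HBEGF differed by −0.91 and −0.65, and the receptor EGFR by −0.02 (probe sets −0.33 to 0.12). That list stood apart as lower without probe sets that can cross-hybridise (median −0.20) and with the floor at percentile 75 (−0.27).

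Of the other signalling lists, none stood apart. YAP and TEAD targets had a median of 0.00 (16 members, percentile 86.4), with F3 at 0.55 and CCN1 at 0.34. Notch pathway genes had a median of 0.02 (16 members, percentile 86.6), with MAML2 at 0.65 and HES2 at 0.55, and probe sets of both genes went both ways. Wnt pathway genes had a median of 0.07 (13 members, percentile 90.2), with WNT10A at 0.42 and FZD1 at −0.40, whose other probe set gave 0.30. Stem cell and clonogenicity genes had a median of 0.06 (16 members, percentile 95.3), and KRT19 was the member past 2-fold. The stem cell list did stand apart as higher under 3 alternatives, among them the median of all probe sets (percentile 99.9).

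Genes of amino acid supply and the unfolded protein response were lower at passage 8. 25 of 28 members were below 0, and the median was −0.27, below all 10000 random lists. CTH was past 2-fold, the cystine transporter gene SLC7A11 differed by −0.69, the stress pseudokinase TRIB3 by −0.66 and DDIT3 by −0.58. Glycolysis and hypoxia genes had a median of 0.06 (30 members, 20 above 0, percentile 99.5). ANGPTL4, a lipase inhibitor, was 2.12-fold higher, and the glucose transporter gene SLC2A1 differed by 0.56. NRF2 targets had a median of 0.09 (24 members, 13 above 0, percentile 99.9). The aldo-keto reductase AKR1C3 was 2.75-fold higher, with 0.22 for its other probe set, and its call was lost with their median (0.84). With the floor at percentile 75 the NRF2 list no longer stood apart, and its median was −0.02. Heat shock genes had a median of 0.12 (16 members, 9 above 0, percentile 99.96), with HSPA1B at 0.999, just under the threshold, and DNAJB4 at 0.57. With the floor at percentile 75 that list did not stand apart (percentile 96.0).

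Cholesterol synthesis genes (19 members, median −0.11, percentile 11.9) and fatty acid and epidermal lipid genes (20 members, median −0.09, percentile 25.3) did not stand apart. TM7SF2 and SC5D (probe sets −0.25 to 0.19) differed by 0.39 and −0.25 in the cholesterol list, and CERS4 and ELOVL7 by 0.33 and −0.23 in the lipid list. Oxidative phosphorylation genes had a median of 0.03 (28 members, percentile 96.3), with NDUFA1 at 0.19 and CYC1 at −0.18. Ribosomal protein genes had a median of 0.03 (31 members, percentile 93.8), with RPL7 and RPL13 at 0.16 each. Metallothioneins had a median of −0.08 (7 members, percentile 27.3), with MT1X at 0.41 and MT1G at −0.28. Replication-dependent histone genes had a median of 0.93 over 5 measured members (percentile 100). H2AC6, below the floor at passage 4, was higher by at least 0.58 on the log2 scale against the floor, so the list's only 2-fold call rests on dim signal. H2BC5 and H2BC12 differed by 0.99 and 0.93, and H4C3 by −0.46. The histone median was 0.14 over 12 members with the floor at percentile 25 (percentile 90.3).

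Markers of other cell types were mostly under the floor. Endothelial markers had a median of 0.22 (5 members, percentile 89.1), with TIE1 at 0.22 and EGFL7 at −0.02 (probe sets −0.22 to 0.12). KDR and VWF lay below the floor at passage 4 and were higher by at least 0.11 and 0.19 against it, and probe sets of VWF went both ways. The melanocyte markers CAPN3 and PMEL, both just below the floor at passage 4, were higher by at least 0.52 and 0.42 against it (3 measured). Of the Merkel cell markers (2 measured), SYP differed by 0.18, and ISL1, below the floor at passage 4, was higher by at least 0.46. Among myeloid markers, TYROBP differed by 0.12, ITGAX by 0.05 and CD68 by 0.01 (3 measured). The lymphocyte markers NKG7 and CD4 differed by 0.08 and −0.06 (2 measured). Eccrine gland markers had 4 measured members, with CA2 at 0.24 and SLC12A2 at −0.16 beside KRT7, which the simple epithelial list also holds. The sebocyte markers FADS2 and MGST1 differed by −0.18 and −0.16 (2 measured), and probe sets of MGST1 spanned −0.16 to 0.15. Reference genes had a median of 0.00 (15 members, percentile 80.7), and their largest differences were −0.32 for IPO8 and −0.29 for TUBB.

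In total 16 lists stood apart as higher, 4 as lower and 17 did not, while 6 had too few measured members. Among independent lists chance would set 5% apart, and the lists share genes, so their calls are not independent. The calls of 12 of the 20 lists held under all 9 alternative settings. These were the wound, S phase, mitosis, kinase inhibitor, senescence-lowered, matrix protease, p53, mesenchymal, interferon, immediate early, glycolysis and amino acid lists. All 9 settings reuse the same arrays, so a call that held was not replicated. The p53 (0.17), mesenchymal (0.17), immediate early (0.16) and glycolysis (0.06) medians were smaller than the largest spiked control difference, 0.23.

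**Figure D3:**
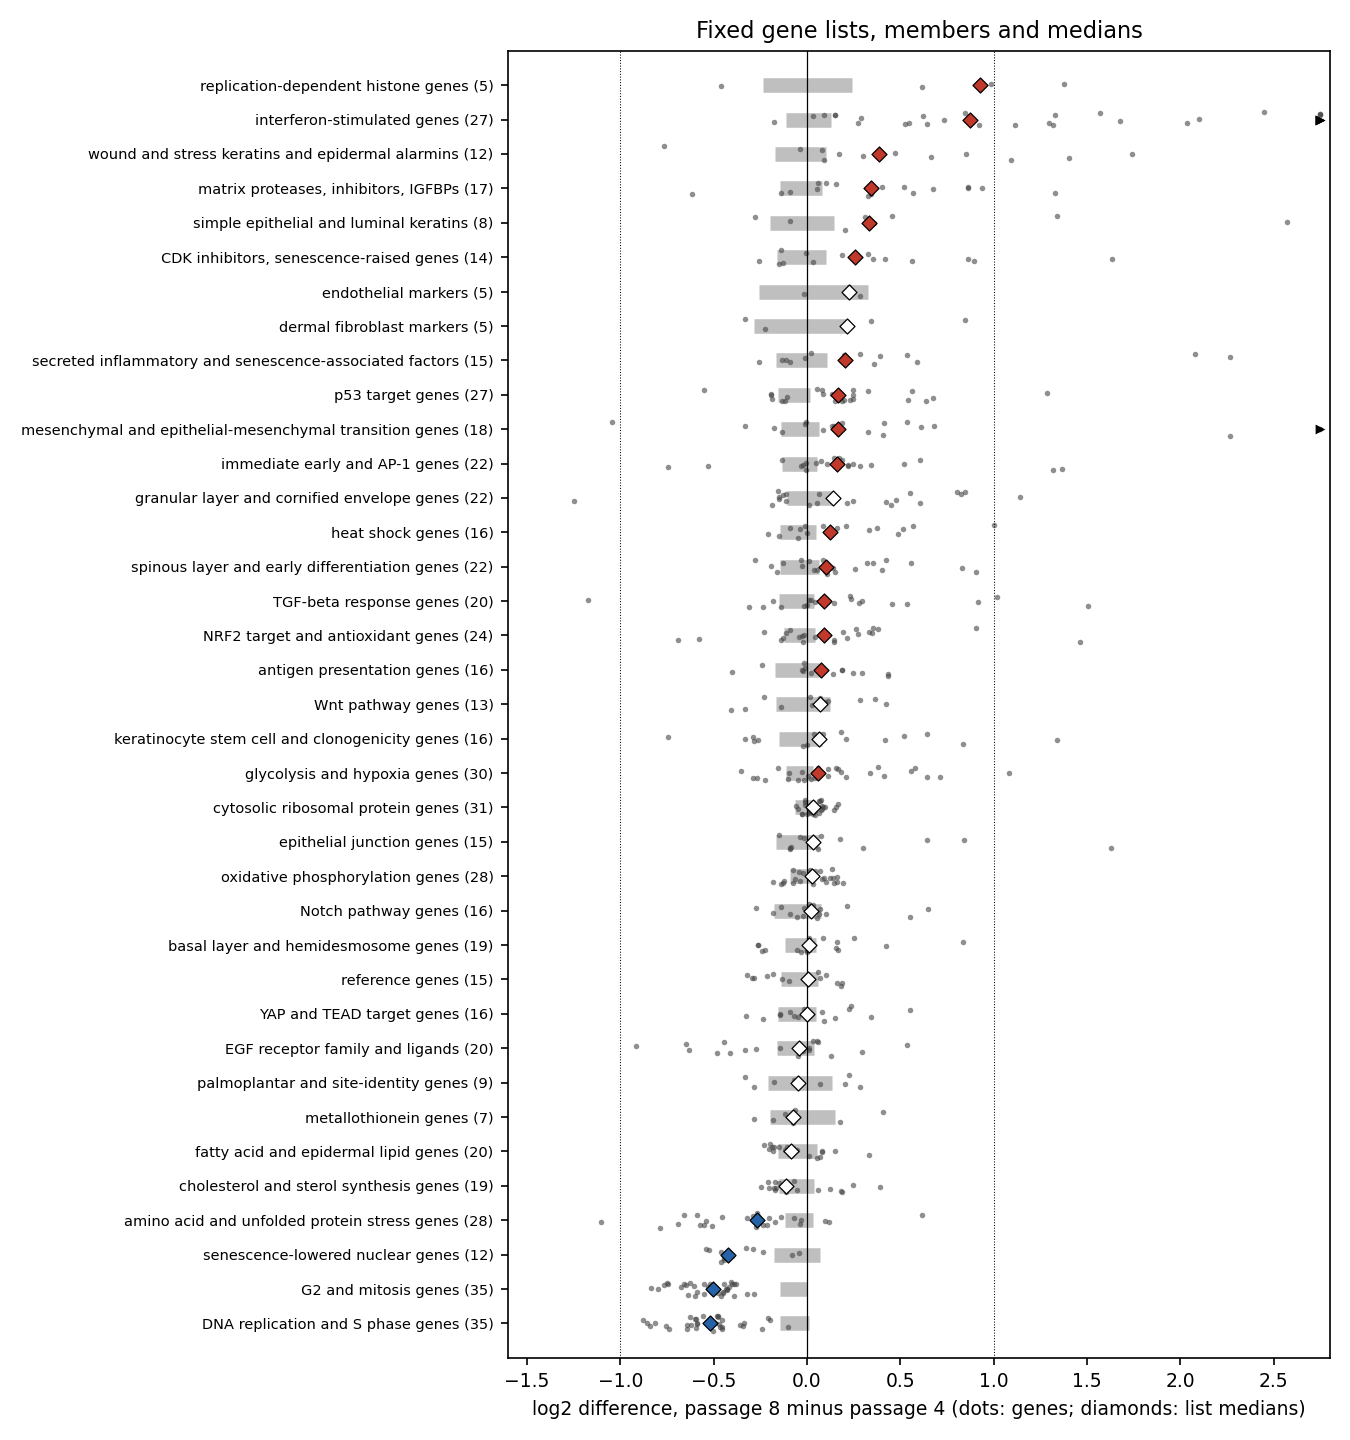
Log2 differences, passage 8 minus passage 4, for the 37 lists with at least 5 measured members (number in brackets). Dots are genes, diamonds are list medians (red higher, blue lower, white not apart), grey bars span 95% of the medians of 10000 random lists, and arrowheads mark members beyond the right edge; the interferon median of 0.87 and the S phase median of −0.52 lie far outside their bars.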

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

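This count was chosen as a check only after the data were seen. Probe sets tied to no gene or to several genes took no part in the gene comparisons, and 18 of the 1973 measured ones were at least 2-fold higher at passage 8, of which 14 were tied to several genes and 4 to none. 1 was at least 2-fold lower. Their largest difference was 3.84, from log2 5.55 to 9.39, and the most negative was −1.11. No gene is named for these signals.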

How the results depend on the processing

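All alternatives were set beforehand except the count with low levels set to the floor, which was chosen after the data were seen. Centring, quantile normalization and lowess kept the gene counts within 1.5 times the main ones and moved no list median by more than the control spread. All 40 named genes past 2-fold stayed past it after centring, 39 after quantile normalization, where TNC fell short, and 38 after lowess, where NAV3 did too. With the median of all probe sets 28 of 40 did, and without probe sets that can cross-hybridise 30 of the 33 that still had a value.

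Genes at least 2-fold higher numbered 28 with the floor at percentile 75, where fewer genes were measured, 194 at 1.5-fold and 24 at 3-fold, against 59. Genes lower numbered 9 with the median of all probe sets, 5 with the floor at percentile 75, 196 at 1.5-fold, 0 at 3-fold and 7 with low levels set to the floor, against 14. The share of higher genes was 49.7% at 1.5-fold and 80.8% at 2-fold, so the lean towards higher genes holds for large differences only.

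With the floor at percentile 75, the secreted factor median reversed to −0.0097 and the NRF2 median to −0.021. Medians there were 1.71 for interferon, 0.59 for wound, 0.61 for granular layer (2 members left), 0.056 for simple keratin (4 left), 0.23 for TGF-beta, −0.27 for EGF receptor, 0.23 for histone (2 left) and 0.044 for eccrine genes. With the floor at percentile 25 the medians were 0.69 for interferon, 0.14 for histone, 0.22 for melanocyte, 0.18 for Merkel cell and 0.059 for sebocyte genes, and with no floor they were 0.64, 0.17, 0.19, 0.13 and 0.027. A floor changes which members are measured, which by construction moves these medians.

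Without probe sets that can cross-hybridise, medians were 0.17 for wound, 0.27 for mesenchymal, 1.02 for interferon, −0.20 for EGF receptor and 0.21 for stem cell genes. CDCA3 reversed to 0.17, on a probe set that lay below the floor on both arrays. With the median level of all probe sets on each array, list medians were 0.32 for granular layer, −0.12 for YAP, 0.61 for histone and −0.14 for endothelial genes (1 left). AQP9 was 0.052, but that value sets the passage 4 level of 1 probe set against the passage 8 level of another. It shows no reversal, since the probe sets of AQP9 differed by −1.40, −0.19 and 0.05. By the same median levels CDKN2A was 0.52, DLX5 −0.63, DLEU2 −0.11 and TP53I11 −0.27. Beyond the change of probe sets, the cause was not tested. With the floor at percentile 75, probe sets of 100% of the multi-probe genes past 2-fold went the same way, and r between the 2 brightest probe sets was 0.85, against 96.2% and 0.72. With the floor at percentile 25 these were 83.3% (35 of 42) and 0.62, and without probe sets that can cross-hybridise 94.4% (17 of 18) and 0.67.

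Some lists stood apart as higher under an alternative only. These were oxidative phosphorylation after lowess, with the median of all probe sets and without probe sets that can cross-hybridise, YAP targets with the floor at percentile 75, fibroblast markers with the floor at percentile 25 and against unmatched random lists, endothelial markers against unmatched random lists, eccrine markers with the floor at percentile 25 or none, and melanocyte markers with no floor. Granular layer and stem cell genes did so too, and EGF receptor genes stood apart as lower under an alternative only. Medians near 0 turned sign under at least 1 alternative for the palmoplantar, basal, junction, YAP, Notch, Wnt, EGF receptor, lymphocyte and reference lists. Larger medians turned sign too. With the median of all probe sets, the fibroblast median went from 0.21 to −0.021 and the endothelial one from 0.22 to −0.14, each with too few members for a call. With the floor at percentile 25, the sebocyte median went from −0.17 to 0.059.

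No paired analysis was possible because each passage has 1 array, so there was also no replicate to leave out. Signal over background limits folds of genes near the floor.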

Other observations

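The symbol groups, the clock and DNA repair lists, and the tests of explanations given here were chosen after the results were seen, except the test of other interferon genes, which was set down first. Genes sharing a symbol stem were compared in the same way as the fixed lists, over 348 stems. Of these, 20 stood apart as higher and 22 as lower, where chance would give 17 in both directions together. Nuclear pore genes (stem NUP) had differences below 0 in 21 of 21 members, with a median of −0.36. Exosome subunits, which degrade RNA (stem EXOSC), were below 0 in 10 of 10 (median −0.31), augmin subunits of the spindle (stem HAUS) in 7 of 7 (−0.33), and centrosomal proteins (stem CEP) in 29 of 32 (−0.26). Mitochondrial ribosome small-subunit genes (stem MRPS) were below 0 in 25 of 27 (−0.17), and proteasome regulatory subunits (stem PSMD) in 12 of 12 (−0.17), against random medians of −0.07 and −0.05. The related stems MRPL (42 of 49 below 0, percentile 3.14), PSMC (5.82), PSMA (3.99) and PSMB (12.2) did not stand apart. CXCL chemokines were above 0 in 6 of 6 measured members (0.38). Keratin-associated proteins of hair (stem KRTAP) were above 0 in 25 of 27 (0.19) and olfactory receptors (stem OR) in 11 of 11 (0.25), so medians of that size also occurred in genes not known for a role in cultured keratinocytes.

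Genes of the Fanconi anaemia and homologous recombination pathways, which repair DNA crosslinks and breaks, had a median of −0.35, with 17 of 19 members below 0 and all 10000 random lists above it. FANCI differed by −0.77. Circadian clock genes had a median of −0.28 over 10 members (percentile 0.39). The clock repressors PER3 and PER2 differed by −0.83 and −0.81, NR1D2 by −0.70, CRY1 by −0.15 and PER1 by −0.14, while BHLHE40 differed by 0.25. The activators BMAL1, NPAS2 and CLOCK differed by 0.20, 0.21 and −0.40, and TEF, a further member, by −0.48. Of these, CRY1, PER1, BMAL1 and NPAS2 differed by less than the largest spiked control difference, 0.23. Only 10 of the 16 members on the array were measured, with CRY2, CIART and BHLHE41 among those below the floor. No split between repressors and activators is therefore read from these values. The hour of harvest was not analysed here, so no reading of the clock values was tested.

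Interferon-stimulated genes and IFNK were higher at passage 8. A difference in array scaling or hybridisation as the cause is argued against by the smallest list median over the deposited and rescaled values, 0.86, since no spiked control differed by more than 0.23. Whether IFNK, a type I interferon that keratinocytes make, is behind the pattern was not tested. Another interferon gene stays open, because none of the 16 other ligand genes on the array reached the floor, and the largest difference among them was 0.88 for IFNE. A difference between the cultures other than passage number, such as a stimulus in the passage 8 culture, cannot be told apart from passage with 1 array per passage.

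Replication and mitosis genes were lower at passage 8. Array scaling or hybridisation is argued against by the list median nearest 0 over the deposited and rescaled values, −0.45, which exceeds in size the largest control difference of 0.23. Dilution of cycling basal cells by differentiated cells that lack basal transcripts would lower basal genes about as much. For the 19 measured basal genes the values argue against it, since their lowest difference was −0.26, against a replication median of −0.52. The basal list median lay 0.53 above the replication median, more than the SD of 0.26 among basal genes. That SD is a spread between genes and not an error. Basal genes that differ for another reason, such as KRT15 (0.84), could mask dilution. Differentiated cells that keep basal transcripts stay open, since the spinous list was higher (percentile 99.5), a call lost under 2 settings, with IVL at 0.83. A difference between the cultures other than passage number, such as confluence at harvest, cannot be told apart from passage with 1 array per passage.

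FN1 and POSTN were higher at passage 8. Whether dermal fibroblasts were in the passage 8 culture cannot be decided, because most of the transcripts checked lay below the floor. Of 6 transcripts abundant in fibroblasts, COL1A1, COL1A2, COL3A1, DCN and LUM lay below it on both arrays. They stood at 2.59 to 5.17 at passage 8, where FN1 reached 11.20. SPARC, over the floor on both, differed by −0.13. None of the 29 probe sets of these 6 genes was 2-fold higher, with 0.31 for COL1A1 as the largest difference. These values leave fibroblasts open, since dim signal could hide a rise. The fixed fibroblast list had a median of 0.21, just inside the random range. It stood apart as higher with the floor at percentile 25 (percentile 99.35) and against unmatched random lists (98.3). It did not after centring, quantile normalization or lowess, or with no floor (69.0), and the other settings left too few members. COL6A1 differed by 0.85, with 0.03 to 0.32 for its other probe sets. COL5A2 and TWIST2, over the floor on both arrays, differed by 0.34 and −0.33. A single cross-hybridising probe set is argued against by 12 of the 13 probe sets of both genes being at least 2-fold higher. A difference between the cultures other than passage number cannot be told apart from passage with 1 array per passage.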
